A study of Mus musculus with 21 samples.

How the data were processed

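Liver RNA of female C57BL/6 mice was measured on 21 microarrays with 2 colours. Per the labels, the mice were given nanosized titanium dioxide (TiO2) through the trachea once, at 162 µg per mouse, or the vehicle alone, and the livers were taken 1 or 28 days later. The vehicle was saline with some cell-free lung lavage fluid of untreated mice. Each array held the labelled RNA of 1 animal in the red dye (Cy5) and a universal mouse reference RNA in the green dye (Cy3), so every array shared the same reference and no dyes were swapped. The labels call the samples biological replicates. The design text of the series speaks of 22 arrays, and 21 were analysed here. The extraction protocol in the labels names lung tissue although the source of every sample is given as liver, so liver and lung markers were counted on each array.

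Groups were taken from the treatment and time labels alone. There were 5 arrays of control mice and 6 of TiO2 mice at day 1, and 4 of control mice and 6 of TiO2 mice at day 28. Replicate numbers follow the order of deposition and name an animal without pairing it with any other. The array headers name 9 slides, with room for 4 arrays each, and 3 scan days, and each scan day holds arrays of all 4 groups. Each group had 2 arrays on each scan day, with 2 exceptions. Either control group had 1 on scan day 1, and the day 28 controls had 1 on scan day 3.

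The scanner files hold 43379 spots that are not controls and 1639 control spots, for 41174 probes. The deposited spot values used here are intensity, the median brightness of the pixels of a spot and of its local background in each channel, with no normalization per the file headers. The deposited LogRatio column is the log10 of the processed red signal over the processed green signal, after background subtraction and dye normalization by the scanner software, per the file headers. That software sets 12.8 to 25.6% of these ratios to exactly 0 on each array. The table of processed values that the authors deposited holds log2 values whose scale, centring and direction are not stated. Set against log2 ratios of red over green from the same arrays, normalized here with no background subtraction, its columns had correlations of 0.9957 to 0.9971 and slopes of 0.991 to 0.993. Its columns had medians of -0.058 to -0.011. The scale and direction of that table were taken from this match. The file headers name Feature Extraction version 10.7.3.1 with a protocol for 2 colours, whereas the submitters' processing notes name version 9.5.3.1. How the authors filtered and tested the values is not given in the sources used here.

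The mean spot signal foreseen for background correction was not among the columns of the files, so the median spot signal took its place. Background was corrected in limma 3.58.1 under R 4.3.3 by the normexp method with an offset of 50, followed by loess within each array with control spots at weight 0. For normexp, spots whose signal or local background the scanner software marked as deviant, 72 to 324 per array, were given the median background of the array's other spots. This was decided after the data were seen, because the fit on all spots failed on control day 28 replicate 4 and TiO2 day 28 replicates 3 and 5, and the fit on all spots is among the alternatives. Marked spots were then left out, saturated spots were kept, and spots of the same probe were averaged. All values below are log2 of liver over reference, and differences between groups are differences of these log2 ratios.

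Probes were kept where the liver channel was well above background, by the scanner software's own test, on at least 50% of the arrays of at least 1 group. This kept 21405 probes. Gene symbols came from the RefSeq accession of each probe through a RefSeq gene table of assembly GRCm38.p6, in the absence of symbols in the files. A symbol was found for 23374 probes, covering 16535 genes, and for 17800 probes none was found. The count of probes whose accession named several genes was 0, by the lookup in that table. The array headers name the older build mm8, so no coordinates are given. Each gene was represented by its probe with the highest mean liver signal, and unnamed probes stood for themselves, which left 17624 features for testing, 11239 of them named genes. Of these, 210 lacked a value on at least 1 array. The other probes of a named gene sometimes gave smaller or opposite values, and many of these are stated beside the gene.

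Each comparison was tested in limma with 1 model of the 4 group means over all 21 arrays, followed by empirical Bayes moderation. Adjusted p-values are by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were TiO2 against control at day 1, the same at day 28, the difference between these effects (day 28 minus day 1), and control at day 28 against control at day 1. Gene lists were tested with camera, which asks whether the genes of a list shift against all other genes, at its preset correlation of 0.01, with adjustment over the 36 lists that had at least 5 measured members. The lists hold 718 genes, of which 684 are on the array and 599 were measured. Camera was run again with a correlation estimated from the data for each list, and with scan day in the model. The self-contained test fry was run as well, and the mean of a list on each array was compared by an ordinary linear model of the 4 groups, which gave the intervals, and by an exact permutation test. Exact permutation tests were two-sided, and so were those of limma and camera, and they ran over all splits of the arrays of a comparison or over those within scan days. Intervals are at the 95% level.

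The design, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule a comparison names up to 10 called genes in each direction and, where fewer than 5 were called, the genes with the smallest unadjusted p up to 5 in each direction, given as not passing. It also names up to 4 members of each list called and, in every comparison, Saa1, Saa2, Saa3, Lcn2, Hp, C3, Mt1, Mt2, Hmox1, Cyp7a1, Alb and Sftpc. Sftpc, a lung surfactant gene, did not pass the filter and has no tested value. A probe not well above background on any array of a group has only a bound there, given as at least a fold, from the mean of the brighter group over the dimmer group's mean of, per array, the lowest level called well above background or the probe's own level if higher. These are liver channel values after loess and Aquantile, open to dye bias without dye swaps. This applied to 1 named gene. Some members of called lists that the rule names are not reported here.

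The 38 lists covered liver processes and markers of liver cell types and of other tissues that a sample could hold. The erythroid list had 5 measured members, 4 of them with a value on every array, and the exocrine pancreas list had 4, so neither was tested.

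The steps were tested on simulated data in which 66 or 67 genes were shifted by each of 3 known folds. The simulation used real residuals, shuffled once among the arrays without regard to scan day. In the day 1 comparison limma recovered 61.2% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold, over 17414 genes, with 17 false calls. There 942 unchanged genes had an unadjusted p under 0.05 in limma. At day 28 the recovered shares were 43.3%, 82.1% and 100%, with 0 false calls by limma and 208 unchanged genes at an unadjusted p under 0.05. For the difference between the effects they were 6%, 55.2% and 93.9%, with 3 false calls and 592 such unchanged genes. For the control groups they were 46.3%, 76.1% and 98.5%, with 1 false call and 389 such unchanged genes. The real day 1 comparison had 305 genes at an unadjusted p under 0.05 in limma. Because the simulated and real data differ in this, the recovered shares need not carry over to the real data. In the same simulation camera at the preset correlation called 5, 3 and 9 lists without any added shift in the day 1, day 28 and control comparisons. With an estimated correlation it called 0 lists, and it also missed an added shift of 0.4 in the acute phase list, with adjusted p of 0.967, 0.16 and 0.295 respectively. The test fry missed the same shift, with adjusted p of 0.624, 0.893 and 0.565. The tests were therefore reported side by side.

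The number of arrays limits the precision of every value. Between 12985 and 26616 probes per array were well above background in the liver channel, and this number followed the scan day. Alternatives fixed in advance covered the background correction, the normexp offset, the normalization between arrays, the authors' values, the scanner software's LogRatio, the liver channel alone, the filter on dim probes, the slide as a fixed or random block, the samples in the model, empirical Bayes settings, array weights, the choice of probe, the list test, the threshold and each array left out in turn. Alternatives chosen after seeing the data were scan day as a block, each scan day left out, normexp on all spots, scaling between arrays, the arrays that the quality report called in range, and the list tests with scan day. For each comparison 100 splits of the same arrays, the real one included, were fitted to count how often another split gave as many genes or lists. Data handling used the R package data.table in version 1.17.8, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.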

Results

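The liver transcriptome was measured in 21 mice that had received titanium dioxide nanoparticles or vehicle into the airways. The question was whether particles deposited in the lung change gene expression in the liver, and whether complement genes are among those that change. Levels are log2 ratios of liver RNA to a common reference RNA, with SD over mice and the SE of limma for differences. There were 5 control and 6 TiO2 mice at day 1, and 4 control and 6 TiO2 mice at day 28, each animal on 1 array.

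All samples carried a liver profile. Each of the 16 hepatocyte markers on the array was well above background on every array, with a median log2 ratio of 5.57 to 7.09 per array. Of 13 lung markers, 3 to 11 were above background, with a median log2 ratio of -0.11 to 0.23. Ager, a marker of alveolar type 1 cells, was above background on 0 of 21 arrays by the scanner software's test, and Sftpc, a surfactant gene, on 2. Sftpd and Cyp2f2 were above background on 21 arrays, Lamp3 on 20, Scgb1a1 on 17, Slc34a2 on 16 and Napsa on 13. The remaining lung markers were so on fewer, Aqp5 on 9, Scgb3a1 on 7, Chia1 on 6, Sftpa1 on 4 and Sftpb on 2. Between 12985 and 26616 probes per array were well above background in the liver channel and between 21160 and 29938 in the reference channel. Arrays of scan day 2 had 20879 to 26616 such liver probes, against 15216 to 16903 on scan day 1 and 12985 to 16755 on scan day 3. The first principal component held 40.1% of the variance, and scan day accounted for 91.7% of it and the groups for 1.5%.

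**Figure D1:**
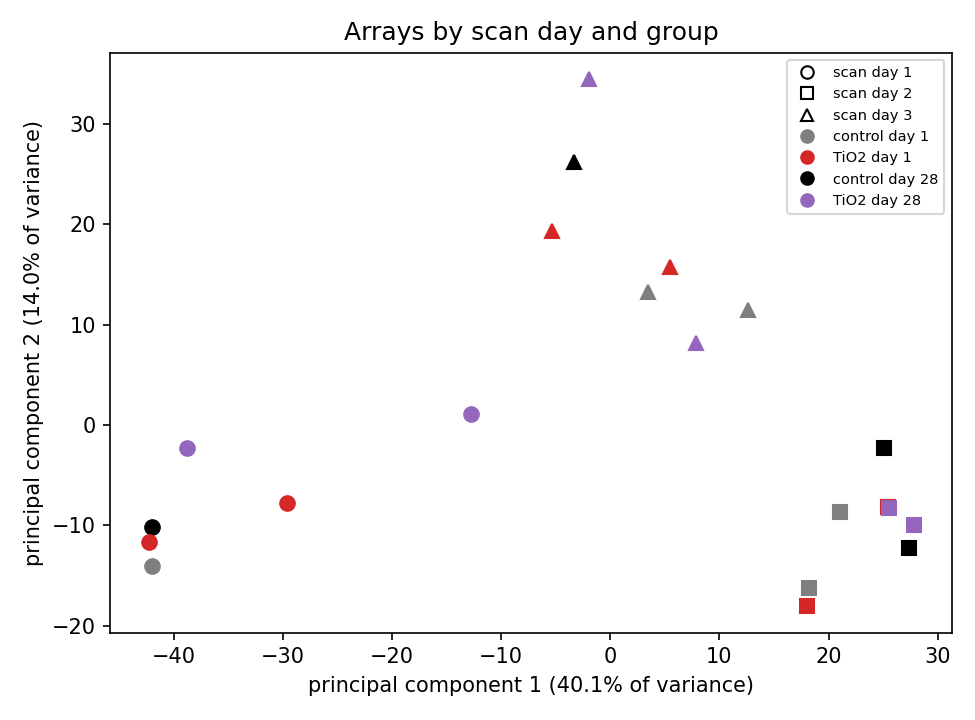
Scores of the 21 arrays on the first principal component (40.1% of the variance) and the second (14%), computed from log2 ratios of liver to reference RNA, with colour for the group and shape for the scan day. The arrays separate by scan day, which accounted for 91.7% of the first component.

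One day after instillation, transcripts of acute phase proteins lay higher in TiO2 livers than in controls, although no single gene passed the test over all genes. The mean difference of the list was 0.38 (95% interval -0.01 to 0.77), and its camera adjusted p = 0.25 with an estimated correlation. Saa3, an inflammation-induced serum amyloid A, had a level of -0.97 ± 0.56 (SD, n = 5) in controls and 1.44 ± 1.46 (n = 6) with TiO2, a difference of 2.41 ± 0.50 (SE) or 5.32-fold. Saa1, an acute phase apolipoprotein made by hepatocytes, went from 3.08 ± 0.48 to 4.86 ± 1.03, a difference of 1.77 ± 0.39. Lcn2, which encodes the iron-siderophore binding protein lipocalin-2, went from 0.38 ± 0.17 to 1.86 ± 0.85, a difference of 1.48 ± 0.27. For all 3 genes 6 of 6 TiO2 mice lay above the control mean. Among them TiO2 day 1 replicate 2 lay within the range of the controls, with Saa1 at 3.085 against a control mean of 3.084. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 4.51 ± 1.17 in controls and 2.91 ± 0.75 with TiO2, a difference of -1.60 ± 0.51 with 0 of 6 TiO2 mice above the control mean.

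In limma 0 of 17624 genes and unnamed probes passed at day 1, with 305 at an unadjusted p under 0.05 (175 higher, 130 lower), where chance would give 881. Without control day 1 replicate 2 the number at an unadjusted p under 0.05 was 479. With scan day as a block the count was again 0, with 720 at an unadjusted p under 0.05. The adjusted p was 0.286 for Lcn2, 0.752 for Saa3 and 1 for Saa1, and with scan day as a block 0.145, 0.152 and 0.152. With slide as a random block, limma called these 3 genes, at 1.55 for Lcn2, 2.51 for Saa3 and 1.87 for Saa1. With slide as a fixed block it called 0, at 1.58, 2.57 and 1.93. Without TiO2 day 1 replicate 2 it also called them, at 1.74, 2.86 and 2.13, and with array weights it called Lcn2 alone, at 1.58. The exact permutation p over the 10 fixed genes with complete values, unadjusted, was 0.00866 for Lcn2, 0.0152 for Saa3, 0.0108 for Saa1 and 0.0325 for Cyp7a1. Adjusted over these genes the exact p was 0.0507 for each of the first 3 and 0.0812 for Cyp7a1. Within scan days 1, 2 and 3 the differences were 1.30, 1.58 and 1.66 for Lcn2, 1.97, 2.09 and 3.41 for Saa3, 1.06, 1.75 and 2.62 for Saa1, and -1.67, -0.53 and -2.77 for Cyp7a1. Differences within a scan day, here and below, rest on 1 or 2 mice per group. Lcn2 was represented by probe A_51_P510156, Saa3 by A_51_P337308, Saa1 by A_52_P318673 and Cyp7a1 by A_52_P84027. The other probe gave 0.96 for Saa1 and -0.41 for Cyp7a1, and Saa1 shares much of its sequence with Saa2, which had a difference of 0.44 ± 0.26. That of Saa2 lay between 0.12 on the arrays in range and 3.05 with the liver channel alone, with 0.16 without control day 1 replicate 1, and that of Cyp7a1 between -2.21 without scan day 2 and -0.96 without scan day 3.

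**Figure D2:**
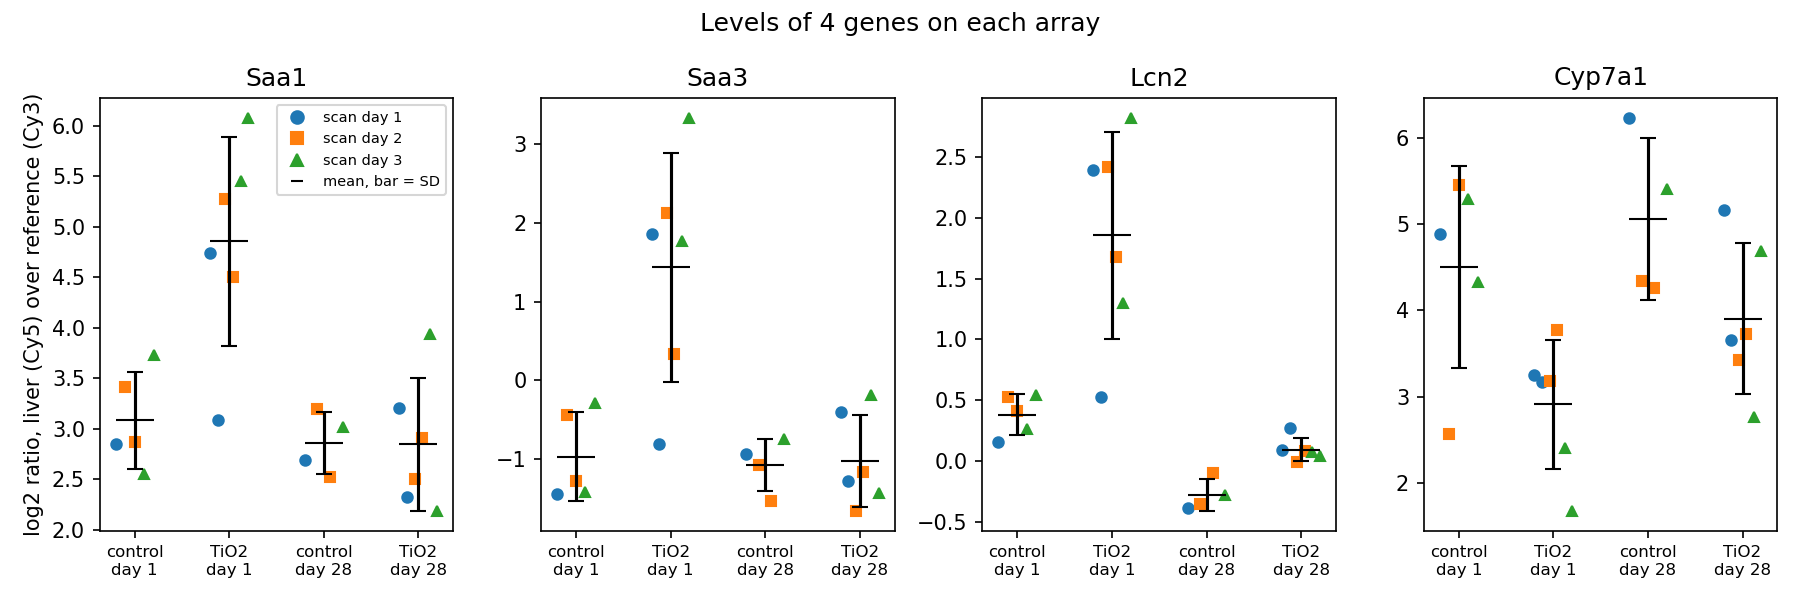
Log2 ratio of liver to reference RNA for Saa1, Saa3, Lcn2 and Cyp7a1 on each array, by group, with the mean and SD of each group and marker shape for the scan day. At day 1 the group means for Saa3 are -0.97 in controls and 1.44 with TiO2, and at day 28 they are -1.08 and -1.02.

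Of the 36 lists, camera called 6 at day 1, 5 higher and 1 lower. In the acute phase list 20 of 26 measured members were higher. Its camera adjusted p was 1.05e-10, and the adjusted p = 0.25 with an estimated correlation. Of its members 0 passed over all genes in limma and 8 had an unadjusted p under 0.05, all higher, and adjusted over the list alone 3 passed, Lcn2, Saa3 and Saa1. Orm3, an orosomucoid, had 0.82 ± 0.29 and Hp, the haemoglobin scavenger haptoglobin, 0.06 ± 0.29. The list's difference was 0.44 (0.20 to 0.68) with scan day in the model, and 0.37, 0.40 and 0.56 within scan days 1, 2 and 3. The handling of scan day changed its tests, since the exact permutation p, unadjusted, was 0.132 over all splits and 0.0185 over those within scan days. Adjusted over the lists, the p over all splits was 0.967. Genes responsive to glucocorticoid had a mean difference of 0.39 (0.03 to 0.74), with 13 of 15 higher and camera adjusted p = 1.57e-06, and the adjusted p = 0.0707 with an estimated correlation. Its members include Lcn2, the only 1 to pass when adjusted over the list alone, Errfi1, a feedback inhibitor of the EGF receptor, at 0.99 ± 0.39, Ddit4, an inhibitor of mTOR signalling, at 0.65 ± 0.33, and the kinase gene Sgk1 at 0.59 ± 0.26. Its difference was 0.42 with scan day in the model and 0.30, 0.66 and 0.30 within scan days. Its exact permutation p, unadjusted, was 0.0844 over all splits and 0.0278 over those within scan days, and again 0.967 adjusted. With both an estimated correlation and scan day in the model camera called 2 lists, the acute phase and the glucocorticoid list.

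The 4 other lists called at day 1 moved less or rested on few mice. Interferon-stimulated genes had a mean difference of 0.14 (-0.07 to 0.36), with 22 of 24 higher (camera adjusted p = 2.95e-05, and adjusted p = 0.651 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, had 0.40 ± 0.12, Irf7 0.32 ± 0.22, Psmb9 0.25 ± 0.13 and Bst2 0.25 ± 0.17, and adjusted over the list alone 0 passed in limma with 1 at an unadjusted p under 0.05. Within scan days this list differed by -0.017, 0.002 and 0.35, and without TiO2 day 1 replicate 6 (0.077) or without the arrays of scan day 3 (0.035) camera no longer called it. PPARA targets, genes of fatty acid oxidation, had a mean difference of -0.19 (-0.55 to 0.17), with 27 of 31 lower (camera adjusted p = 0.000179, and adjusted p = 0.651 with an estimated correlation). Its members Acaa1a, a peroxisomal thiolase, stood at -0.31 ± 0.10 (0.011 and -0.29 at its other probes), Acadm at -0.40 ± 0.27, Acadl at -0.28 ± 0.19 (-0.10 without control day 1 replicate 1) and Cpt1a at -0.25 ± 0.15 (-0.047 at its other probe). The differences within scan days were -0.30, -0.059 and -0.11, and camera no longer called the list without TiO2 day 1 replicate 2 (-0.11) or on the arrays that the quality report called in range (-0.047).

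Immediate early genes had a mean difference of 0.16 (-0.18 to 0.50), with 14 of 19 higher (camera adjusted p = 0.0334, and adjusted p = 0.822 with an estimated correlation). Nr4a1, an orphan nuclear receptor, had 1.14 ± 0.37, Myc 0.41 ± 0.21 (0.31 at its other probe), Dusp1 0.27 ± 0.20 (0.002 to 0.49 over the alternatives) and Klf4 0.23 ± 0.14. Neutrophil markers had 0.34 (0.06 to 0.62), with 4 of 6 higher (camera adjusted p = 0.0465, and adjusted p = 0.651 with an estimated correlation). Lcn2, which hepatocytes also make, belongs to this list and was its 1 member to pass adjusted over the list alone, while S100a9 had 0.47 ± 0.39 (0.20 without TiO2 day 1 replicate 6, 0.71 without control day 1 replicate 2), Chil3 0.18 ± 0.18 (0.091 without control day 1 replicate 3) and Csf3r -0.17 ± 0.11. With scan day as a block neither list was called, each with an adjusted p of 0.0535, and the differences were 0.15 and 0.36. Neither was called with the liver channel alone (0.11 and 0.26), with no filter on dim probes (0.16 and 0.34), without scan day 2 (0.13 and 0.38) or without scan day 3 (0.14 and 0.28). Neutrophil markers were also lost with a normexp offset of 10 (0.39), with only the groups compared (0.34), with normexp on all spots (0.33) and with scaling between arrays (0.35). Within scan days 1, 2 and 3 the differences were 0, 0.14 and 0.23 for immediate early genes and 0.34, 0.28 and 0.45 for neutrophil markers. Immediate early genes were not called without control day 1 replicate 3 (-0.012) or 4 (0.16), or without TiO2 day 1 replicate 1 (0.16), 2 (0.13) or 6 (0.081). Neutrophil markers were not called without control day 1 replicate 1 (0.32), 3 (0.31) or 4 (0.29), or without TiO2 day 1 replicate 1 (0.32), 3 (0.33), 4 (0.35) or 6 (0.23).

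**Figure D3:**
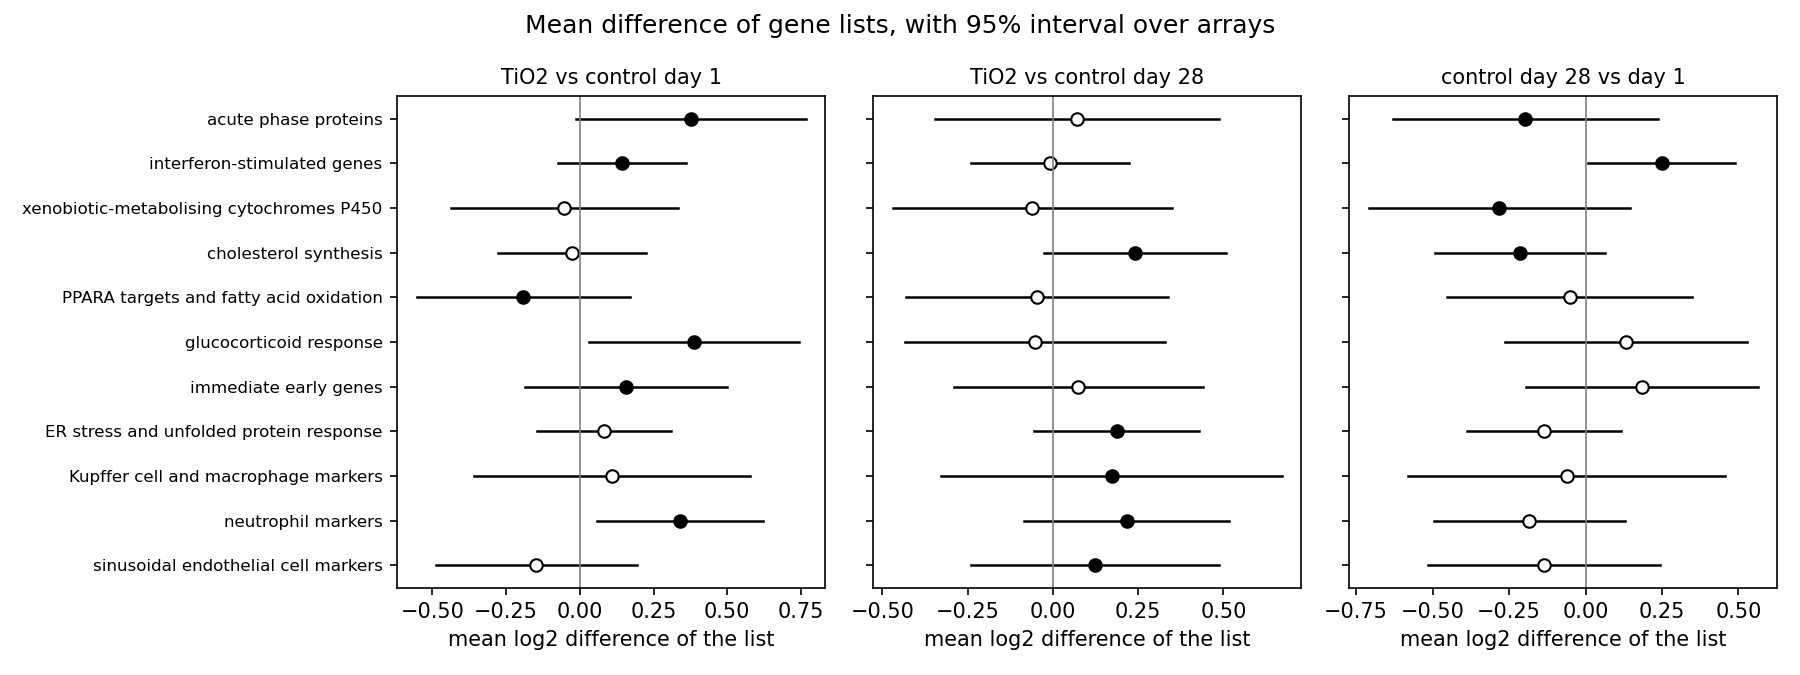
Mean log2 difference of 11 gene lists with its 95% interval, for TiO2 against control at day 1, the same at day 28, and control at day 28 against control at day 1, with filled markers where camera had an adjusted p under 0.05 at the preset correlation. The acute phase list lies at 0.38 on day 1, and the interval there reaches from -0.01 to 0.77.

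Complement genes did not pass at day 1. Their mean difference was 0.075 (-0.26 to 0.41), with 13 of 28 members higher and 15 lower, and their median of -0.023 had the opposite sign to the mean. The camera adjusted p was 0.122, and with scan day as a block camera called the list at 0.14 (-0.017 to 0.30), adjusted p = 0.000573, where the adjusted p = 0.513 with an estimated correlation. Within scan days it differed by 0.22, 0.05 and 0.20. C3, the central complement component, had 0.22 ± 0.11 with an exact permutation p of 0.0909. The 30 lists not called had mean differences from -0.15 to 0.17 and adjusted p of 0.0919 or more.

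Other genes with the smallest p at day 1 did not pass either. Slc3a1, a subunit of an amino acid transporter, had a difference of 0.89 ± 0.27. Lower values were those of Irf1, an interferon regulatory factor, at -0.45 ± 0.14 (-0.10 at its other probe), Cflar, an inhibitor of caspase-8, at -0.37 ± 0.12 (-0.015 and -0.10 at its other probes), and Thumpd1 at -0.36 ± 0.10. Mtus2 was not well above background on any TiO2 array and was so on 3 of 5 control arrays. Its bound from the group means was at least 1.31-fold higher in controls (fitted -0.44 ± 0.12, adjusted p = 1). That bound carries no sampling error, so it does not establish a difference. The metallothionein genes Mt1 and Mt2 had 0.47 ± 0.35 and 0.60 ± 0.60 (0.18 and 0.14 without control day 1 replicate 3), Hmox1, which encodes haem oxygenase 1, had -0.13 ± 0.25, and albumin (Alb) had -0.022 ± 0.16.

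At day 28 Saa1 and Saa3 lay near their controls, and genes of cholesterol synthesis lay higher in TiO2 livers as a group. The mean difference of that list was 0.24 (-0.03 to 0.51), its camera adjusted p = 0.464 with an estimated correlation, and TiO2 mice at day 28 differed from the day 1 controls by 0.028. Saa1 differed by -0.013 ± 0.42 and Saa3 by 0.054 ± 0.53. Mvd, mevalonate diphosphate decarboxylase, went from -0.22 ± 0.35 (SD, n = 4) in controls to 0.55 ± 0.44 (n = 6) with TiO2, a difference of 0.76 ± 0.29 or 1.70-fold. Cyp7a1 stood at 5.06 ± 0.94 in controls and 3.91 ± 0.88 with TiO2, a difference of -1.16 ± 0.54, with -0.56 at its other probe. It lay between -1.77 with the LogRatio of the scanner software and -0.36 on the arrays in range, with -0.77 without control day 28 replicate 1. Lcn2 differed by 0.37 ± 0.28 (1.84 with the same LogRatio), from -0.28 ± 0.13 to 0.09 ± 0.09, and was well above background on 2 of 4 control and 5 of 6 TiO2 arrays. The SE of limma rests on 1 spread shared by all groups. For Lcn2, Saa1 and Saa3 the spread was widest in TiO2 mice at day 1, so their SE at day 28 reflects that group too.

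In limma 0 genes passed at day 28, with 160 at an unadjusted p under 0.05 (62 higher, 98 lower) and a smallest adjusted p of 1. Without control day 28 replicate 1 or 3 the number at an unadjusted p under 0.05 was 264 or 258. With scan day as a block the count was again 0 in limma, with 542 at an unadjusted p under 0.05. For Lcn2 the exact permutation p was 0.00476, and 0.0476 adjusted over the 10 fixed genes. With splits kept within scan days the exact p was 0.0185, the smallest that these 54 splits can give, and 0.185 adjusted, so a single gene could not pass there. Within scan days the differences were 0.57, 0.26 and 0.34. The day 28 controls differed from the day 1 controls by -0.66 for Lcn2 (exact permutation p 0.00794, adjusted 0.0794). All TiO2 mice at day 28 lay below the day 1 control mean of Lcn2 too. The effect of TiO2 on Lcn2 at day 28 and a low level of the day 28 controls thus cannot be told apart here. For Cyp7a1 the exact permutation p was 0.0905, adjusted 0.452, with differences of -1.82, -0.73 and -1.68 within scan days. Among the genes with the smallest p, Apcs, which encodes serum amyloid P, had 0.53 ± 0.18, the tetraspanin gene Cd9 0.48 ± 0.16, the apoptosis gene Bcl2l11 0.39 ± 0.13, Nhsl1 0.39 ± 0.13 and Zfp111 0.27 ± 0.09. Lower values were those of Nrg4, a growth factor of the EGF family, at -0.48 ± 0.16, Oxt at -0.40 ± 0.14, Usp2 at -0.35 ± 0.11, Llph at -0.32 ± 0.10 and Utp25 at -0.25 ± 0.08. Oxt and Utp25 were above background on 2 of 4 control and 2 of 6 TiO2 arrays, and Usp2 on 2 and 1. Saa2 had -0.093 ± 0.28, Hp -0.072 ± 0.30, C3 -0.001 ± 0.12, Mt1 -0.49 ± 0.38 and Mt2 -0.83 ± 0.64 (-0.22 and -0.43 without control day 28 replicate 4), Hmox1 -0.034 ± 0.29 and Alb -0.12 ± 0.17.

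Camera called 5 lists at day 28, all higher, and with an estimated correlation 0, while members of these lists adjusted over the list alone were 0 in limma, with 5, 1, 0, 0 and 0 at an unadjusted p under 0.05 in the order given here. Cholesterol synthesis had 20 of 23 members higher (camera adjusted p = 1.6e-09, and adjusted p = 0.464 with an estimated correlation). Besides Mvd, its members Hmgcs1, the synthase at the start of the pathway, had 0.49 ± 0.22 (0.15 at its other probe), Msmo1 0.43 ± 0.18 and Sqle, squalene epoxidase, 0.37 ± 0.17. Its difference was 0.22 with scan day in the model and 0.55, 0.064 and 0.21 within scan days. Genes of the unfolded protein response had 0.19 (-0.05 to 0.43), with 15 of 20 higher (camera adjusted p = 0.00253, and adjusted p = 0.464 with an estimated correlation), among them the disulfide isomerase gene Pdia6 at 0.29 ± 0.13 (0.059 and 0.26 at its other probes), Sdf2l1 at 0.44 ± 0.30 (0.22 without control day 28 replicate 4), Xbp1 at 0.30 ± 0.21 and Hsp90b1 at 0.25 ± 0.20 (0.13 at its other probe). Within scan days they differed by 0.28, -0.037 and 0.45. With scan day in the model the difference was 0.19, and the list was not called without control day 28 replicate 4 (0.11) or TiO2 day 28 replicate 1 (0.16), with array weights (0.077), without scan day 3 (0.093) or on the arrays in range (-0.043).

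Markers of 3 cell types were called at day 28 with larger uncertainty. Kupffer cell markers had 0.17 (-0.33 to 0.67), with 14 of 15 higher (camera adjusted p = 0.0375, and adjusted p = 0.974 with an estimated correlation), among them C1qb at 0.48 ± 0.23, Vsig4 at 0.37 ± 0.32 (0.19 without control day 28 replicate 4), Lyz2 at 0.30 ± 0.25 (0.078 at its other probe) and Csf1r at 0.20 ± 0.18 (0.036 at its other probe). Over the alternatives Lyz2 lay between 0.098 and 0.475 and Csf1r between 0.087 and 0.352. Sinusoidal endothelial markers had 0.12 (-0.24 to 0.49), with 13 of 15 higher (camera adjusted p = 0.0389, and adjusted p = 0.974 with an estimated correlation), among them Fcgr2b at 0.27 ± 0.22 (0.14 and 0.26 at its other probes), Ehd3 at 0.25 ± 0.22, Dnase1l3 at 0.24 ± 0.24 and Stab2 at 0.20 ± 0.12. In the alternatives these 4 genes had 0.116 to 0.412, 0.115 to 0.352, -0.347 to 0.417 and 0.066 to 0.398. Neutrophil markers had 0.22 (-0.08 to 0.52), with 5 of 6 higher (camera adjusted p = 0.0389, and adjusted p = 0.76 with an estimated correlation), among them S100a9 at 0.56 ± 0.41 (0.28 without control day 28 replicate 1, 0.90 without replicate 2), Chil3 at 0.17 ± 0.19 and Mpo at 0.12 ± 0.12, the last above background on 2 of 4 control and 2 of 6 TiO2 arrays. Within scan days the differences were -0.02, 0.39 and 0.32 for Kupffer cells, 0.077, 0.18 and 0.37 for sinusoidal endothelium, and 0.36, 0.23 and 0.12 for neutrophils. With scan day in the model they were 0.22, 0.17 and 0.23, and camera no longer called the neutrophil list (adjusted p = 0.0917). All 3 calls were lost with no filter on dim probes, at unchanged differences of 0.17, 0.12 and 0.22 for Kupffer cells, sinusoidal endothelium and neutrophils. In the same order all were lost with the scanner software's LogRatio (0.10, 0.052 and 0.31), with no background correction (0.14, 0.085 and 0.21), with the authors' values (0.14, 0.074 and 0.20), with array weights (0.035, -0.024 and 0.14) and with normexp on all spots (0.14, 0.012 and 0.12). Kupffer cells and sinusoidal endothelium were also lost with a normexp offset of 10, at larger differences (0.19 and 0.15), and without scan day 3 (0.11 and 0.031). Kupffer cells and neutrophils were lost without scan day 2 (0.15 and 0.24), and neutrophils with the liver channel alone (0.12), with scaling between arrays (0.21), without scan day 1 (0.18) and on the arrays in range (0.16). Each of these lists was lost when any 1 of 6 arrays was left out. For Kupffer cells these were control day 28 replicate 1 (0.083), 3 (0.16) or 4 (0.15) and TiO2 day 28 replicate 3 (0.11), 4 (0.077) or 5 (0.11). For sinusoidal endothelium they were control day 28 replicate 1 (0.012), 3 (0.14) or 4 (0.06) and TiO2 day 28 replicate 3 (0.058), 4 (0.06) or 6 (0.094). For neutrophils they were control day 28 replicate 1 (0.15), 2 (0.23) or 3 (0.24) and TiO2 day 28 replicate 1 (0.21), 3 (0.17) or 5 (0.20).

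Complement genes had a mean difference of 0.10 (-0.26 to 0.46) at day 28, with 17 of 28 higher, and camera did not call them (adjusted p = 0.0882). With scan day as a block they were called at 0.14 (-0.029 to 0.30), adjusted p = 0.0049, where the adjusted p = 0.604 with an estimated correlation, and within scan days they differed by 0.13, 0.068 and 0.29. The 31 lists not called had mean differences from -0.13 to 0.10.

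The change from day 1 to day 28 in the TiO2 effect was tested as an interaction. Saa3 had a difference between effects of -2.36 ± 0.73, Saa1 of -1.78 ± 0.57 and Lcn2 of -1.10 ± 0.39 (-0.42 with the scanner software's LogRatio), all lower at day 28. Hmgcs1 had 0.96 ± 0.31, with 0.15 at its other probe, and Zfp111 had 0.44 ± 0.13. The scaffold gene Strn had -0.47 ± 0.15 and the olfactory receptor gene Olfr1282 -0.46 ± 0.16. However, Strn was above background on 1 of 5 control arrays at day 1, and Olfr1282 on 1 of 5 control and 2 of 6 TiO2 arrays at day 1 and 2 of 4 and 2 of 6 at day 28. Shld2, with a role in DNA repair, had 0.72 ± 0.26, with -0.11 and -0.06 at its other probes, Colec10, a collectin, 0.53 ± 0.20, and Bahd1 0.36 ± 0.14, with -0.14 at its other probe. For Cyp7a1 the effects differed by 0.44 ± 0.75, and by -0.15 at its other probe. The other fixed genes had -1.42 ± 0.88 for Mt2, -0.96 ± 0.52 for Mt1, -0.54 ± 0.38 for Saa2 (-3.14 with the liver channel alone), -0.22 ± 0.17 for C3, -0.13 ± 0.42 for Hp, 0.096 ± 0.38 for Hmox1 and -0.098 ± 0.24 for Alb. In limma 0 genes passed, with 131 at an unadjusted p under 0.05 (51 higher, 80 lower), which was 224 without control day 1 replicate 2 and 233 without TiO2 day 28 replicate 1. Once scan day was a block 0 passed again in limma, with 521 at an unadjusted p under 0.05.

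Camera called 5 lists for this difference, and with an estimated correlation 0, while adjusted over the list alone 0 members passed in limma, with 4, 1, 1, 1 and 0 at an unadjusted p under 0.05 in the order given here. The acute phase list had -0.31 (-0.88 to 0.27), with 21 of 26 lower (camera adjusted p = 0.00022, and adjusted p = 0.976 with an estimated correlation), Orm3 among them at -0.88 ± 0.42. Glucocorticoid-responsive genes had -0.44 (-0.96 to 0.08), with 13 of 15 lower (camera adjusted p = 0.00022, and adjusted p = 0.34 with an estimated correlation), Errfi1 at -1.09 ± 0.57. Cholesterol synthesis had 0.27 (-0.10 to 0.64), with 19 of 23 higher (camera adjusted p = 4.86e-05, and adjusted p = 0.976 with an estimated correlation), Mvd at 0.83 ± 0.40, Msmo1 at 0.46 ± 0.24 and Mvk at 0.37 ± 0.20. Interferon-stimulated genes had -0.15 (-0.47 to 0.17), with 20 of 24 lower (camera adjusted p = 0.00178, and adjusted p = 0.976 with an estimated correlation), Ifit1 at -0.48 ± 0.18, Ifit3 at -0.36 ± 0.32 and Bst2 at -0.32 ± 0.24. Sinusoidal endothelial markers had 0.27 (-0.23 to 0.77), with 14 of 15 higher (camera adjusted p = 0.00133, and adjusted p = 0.976 with an estimated correlation), Dnase1l3 at 0.62 ± 0.33, Clec4g at 0.47 ± 0.38, Fcgr2b at 0.42 ± 0.30 (0.24 and 0.53 at its other probes) and Stab2 at 0.29 ± 0.17. With scan day in the model these 5 differences were -0.35, -0.47, 0.25, -0.17 and 0.28. The acute phase list was not called without control day 1 replicate 1 (-0.20), with normexp on all spots (-0.25), with scaling between arrays (-0.22) or without scan day 2 (-0.21). Interferon-stimulated genes were lost with slide as a fixed block (-0.082), with normexp on all spots (-0.11), without scan day 3 (-0.013) and on the arrays in range (-0.15). The sinusoidal list was lost with the LogRatio (0.25), array weights (0.17), normexp on all spots (0.17) and without scan day 3 (0.11), and the glucocorticoid list without scan day 2 (-0.039). With 1 array left out, the sinusoidal list was not called without control day 28 replicate 1 (0.16) or 4 (0.21), nor the interferon list without control day 28 replicate 2 (-0.094) or 4 (-0.12) or TiO2 day 1 replicate 6 (-0.085). Complement genes differed by 0.025 (-0.47 to 0.52), camera adjusted p = 0.898, and the 31 lists not called lay between -0.21 and 0.15.

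The control groups of the 2 time points give the background for these effects. Coq10b, which encodes a coenzyme Q binding protein, went from 0.20 ± 0.29 (SD, n = 5) at day 1 to 1.32 ± 0.63 (n = 4) at day 28, a difference of 1.12 ± 0.23 or 2.18-fold, with 0.65 and 0.76 at its other probes and 0.53 without scan day 2. Ifit1 went from 0.13 ± 0.10 to 0.79 ± 0.18, a difference of 0.66 ± 0.14. Cyp2b10, a cytochrome P450 induced by xenobiotics, stood at 3.38 ± 1.06 and 1.93 ± 0.59, a difference of -1.44 ± 0.39, and Cyp2c54 had -1.09 ± 0.27. The cell cycle gene Ccnd1 had 0.72 ± 0.17, the transcription factor gene Klf4 0.65 ± 0.16, Slc25a32, a mitochondrial folate carrier, 0.58 ± 0.15, Irf1 -0.64 ± 0.15 (-0.23 at its other probe), Sowahb -0.65 ± 0.17 and the Polycomb gene Cbx2 -0.63 ± 0.14. The fixed genes had -0.66 ± 0.29 for Lcn2 (-2.27 with the scanner software's LogRatio), -0.23 ± 0.43 for Saa1, 0.17 ± 0.29 for Saa2, -0.10 ± 0.55 for Saa3, -0.063 ± 0.32 for Hp, 0.064 ± 0.13 for C3 (-0.24 at its other probe), -0.19 ± 0.39 for Mt1, 0.008 ± 0.67 for Mt2, -0.44 ± 0.30 for Hmox1 (-0.17 without control day 1 replicate 1), 0.56 ± 0.57 for Cyp7a1 (0.074 without control day 1 replicate 2) and -0.048 ± 0.18 for Alb. For Lcn2, with 0 of 4 day 28 mice above the day 1 mean, the exact permutation p was 0.00794, adjusted 0.0794.

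In limma 0 genes passed between the control groups, with 529 at an unadjusted p under 0.05 (318 higher, 211 lower), more than between TiO2 and control at either day. With scan day as a block the count was 0 in limma, with 1363 at an unadjusted p under 0.05. The smallest adjusted p was 0.721, for Coq10b and Ifit1. With array weights limma called 8, of which the named genes were Klf4 at 0.82, Cbx2 at -0.69, Coq10b at 1.29, Ppp1r3c at -1.40 and Sowahb at -0.77, Ppp1r3c being named after its value was seen. Without control day 1 replicate 4 it called 1, the unnamed probe A_52_P608474 at -1.22.

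Camera called 4 lists between the control groups, and with an estimated correlation 0, where the adjusted p = 0.91 with an estimated correlation for each. Interferon-stimulated genes had 0.25 (0.01 to 0.49), with 20 of 24 higher (camera adjusted p = 5.02e-08) and 0.076 with normexp on all spots, among them Ifit3 at 0.73 ± 0.24, Gbp3 at 0.59 ± 0.21 and Usp18 at 0.58 ± 0.19, and Ifit1 was the 1 member to pass adjusted over the list alone. Cytochromes P450 had -0.28 (-0.71 to 0.14), with 19 of 23 lower (camera adjusted p = 3e-05), and 4 passed adjusted over the list alone, Cyp2c54, Cyp2b10, Cyp3a13 at -0.50 ± 0.13 and Cyp2c39 at -0.49 ± 0.16, of which the last 2 turned sign with the scanner software's LogRatio (0.24 and 0.084). Cholesterol synthesis had -0.21 (-0.49 to 0.07), with 19 of 23 lower (camera adjusted p = 0.000215), among them Mvd at -0.66 ± 0.30, Insig1 at -0.44 ± 0.25 (-0.22 without control day 28 replicate 1) and Fdft1 at -0.29 ± 0.16 (0.049 at its other probe). Acute phase genes had -0.20 (-0.63 to 0.24), with 20 of 26 lower (camera adjusted p = 0.00362), among them Fgl1 at -0.47 ± 0.23, Apcs at -0.41 ± 0.19 and Orm2 at -0.41 ± 0.26. Over all genes 0 members of these lists passed in limma, with 7, 6, 2 and 2 at an unadjusted p under 0.05, and adjusted over the list alone 0 passed for cholesterol synthesis and acute phase genes in limma. Within scan days the differences were 0.083, 0.27 and 0.35 for interferon-stimulated genes, -0.34, -0.12 and -0.30 for P450 genes, -0.45, 0.041 and -0.34 for cholesterol synthesis, and -0.098, -0.11 and -0.28 for acute phase genes. With scan day in the model they were 0.26, -0.23, -0.20 and -0.15. With slide as a block the cholesterol list (-0.12) and the acute phase list (-0.057) were not called, nor without scan day 3 (-0.12 and -0.11), nor was the cholesterol list with the liver channel alone (-0.16). P450 genes were not called without control day 28 replicate 1 (-0.14), cholesterol synthesis without that array (-0.14) or control day 1 replicate 4 (-0.13). Acute phase genes were not called without control day 1 replicate 2 (-0.18), 4 (-0.16) or 5 (-0.14) or control day 28 replicate 1 (-0.092). Complement genes had -0.097 (-0.47 to 0.28), camera adjusted p = 0.223, and the 32 lists not called lay between -0.18 and 0.18, of which 2, immediate early genes and cell cycle genes, had a member that passed adjusted over the list alone.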

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

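The tests of scan day and of neutrophils for the acute phase genes, those of scan day and of the day 28 controls for cholesterol synthesis, and that of scan day for the low gene counts were chosen after the result was seen, and the neutrophil test was narrowed to its 2 brightest markers after a first result over 5 markers (0.11) was seen.

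Camera at the preset correlation called a difference in the TiO2 effect between day 1 and day 28 for 5 lists. The adjusted p for the difference was 0.00022 for acute phase genes, 0.00022 for glucocorticoid-responsive genes, 0.00178 for interferon-stimulated genes, 4.86e-05 for cholesterol synthesis and 0.00133 for sinusoidal endothelial markers. With an estimated correlation 0 of these passed in camera, and 0 passed in fry. In simulated data of the day 1, day 28 and control comparisons both tests also missed a shift of 0.4 added to the acute phase list. Camera at the preset correlation called 5, 3 and 9 lists there without any added shift, and this difference was not simulated for lists. Other splits of the arrays called a median of 8 lists for this difference, against 5 for the real one. The number of calls was thus not above that of chance splits.

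The higher acute phase list at day 1 was set against 3 other explanations. A scan day difference is argued against, since the list differed by 0.441 (0.20 to 0.68) with scan day in the model, above the bound of 0.188. A single array as the source of the observed mean is argued against as well. The lowest value with each array left out in turn was 0.263, without TiO2 day 1 replicate 6. This concerns the point value only, since the interval over all arrays, -0.01 to 0.77, includes the bound. RNA of neutrophils may account for little of the Lcn2 signal, because S100a9 and Chil3, the markers above background on all arrays, differed by 0.328 (-0.14 to 0.79) and Lcn2 by 0.87 to 2.09 at the same level of confidence. This narrow gap rests on 2 genes and is not secure. It concerns Lcn2 alone and not the other members of the acute phase list. S100a9 had 0.20 without TiO2 day 1 replicate 6 and up to 0.95 over the alternatives, and Chil3 had 0.091 to 0.41. That chance parted the mice this way stays open, so a response of the liver to particles in the lung is a hypothesis only.

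For the higher cholesterol synthesis list at day 28, a single array as the source of the observed mean is argued against. The lowest value with each array left out in turn was 0.167, without control day 28 replicate 1. This too concerns the point value only, since the interval over all arrays, -0.026 to 0.51, includes the bound of 0.121. With scan day in the model the value was 0.22, against 0.24 without it, and camera still called the list (adjusted p = 0.604 with an estimated correlation and scan day). Adding scan day thus moved the mean little, but scan day stays open because the interval of -0.049 to 0.49 includes the bound of 0.121 and 0. The interval without scan day, -0.026 to 0.51, includes both as well, so this test could not have decided. A low day 28 control group also stays open, because TiO2 mice at day 28 differed from the day 1 controls by 0.028 (-0.22 to 0.28) and the day 28 controls from the day 1 controls by -0.21. The effect of TiO2 and the level of these 4 control mice cannot be told apart here.

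Fewer genes than chance would give had an unadjusted p under 0.05, for which scan day is a candidate explanation, since the median residual SD was 0.233 without it and 0.179 with it, and the gene count at an unadjusted p under 0.05 was higher with it in every comparison. With slide as a block that SD was 0.162. The counts were then 776, 497, 362 and 1274 for day 1, day 28, their difference and the controls. Slides lie within scan days, so these values do not single out scan day. With scan day as a block the counts for day 1, day 28 and their difference (720, 542 and 521) stayed below the nominal 881. That for the controls (1363) lay above. Of 100 splits of the same arrays, the real one included, 80 gave as many such genes as day 1 (305, highest other 5172), 90 as day 28 (160, highest other 5594), 99 as their difference (131, highest other 5070) and 73 as the controls (529, highest other 4568). The medians of the other splits were 563, 327, 666 and 752, also below 881. With scan day as a block these medians were 895, 716, 804 and 1007, which lie on both sides of 881. How much of the shortfall scan day accounts for therefore stays open. As many lists came from 70 splits at day 1 (6, highest other 16), 75 at day 28 (5, highest other 16), 82 for the difference (5, highest other 17) and 71 for the controls (4, highest other 16). Once scan day was a block, as many genes came in the same order from 71, 74, 82 and 17 splits (720, 542, 521 and 1363, highest others 2010, 1620, 1709 and 2156) and as many lists from 42, 62, 53 and 77 (8, 5, 6 and 4, highest others 17, 18, 18 and 15). Chance cannot be excluded for any of these counts. Splits that call more genes than the real one, in the same order up to 299, 2224, 13 and 13, point to a structure of the samples. Once scan day was a block any split called at most 4, 4, 1 and 14 genes, which was fewer except for the controls.

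Single mice stood apart from their group in 22 of 391 groups of values tested, over 87 genes and 11 lists, and chance gives about 1 in 20. Scan day was not taken into account. Replicate 1 of either control group was its only array of scan day 1, and control day 28 replicate 4 its only array of scan day 3. For these, the mouse and the scan day cannot be told apart. Hp was also lowest on the scan day 1 arrays of TiO2 mice (6.15 and 5.33 at day 1, 6.00 and 6.06 at day 28). The gap to the nearest other mouse is given as a share of the range of the group, and levels are log2 ratios. TiO2 day 1 replicate 1 stood apart for Cd9 at -3.09 against -2.68 to -2.46 (gap 0.646) and Errfi1 at 2.24 against 3.21 to 3.53 (gap 0.753). TiO2 day 1 replicate 4 stood apart for Sowahb at 0.89 against 0.35 to 0.52 (gap 0.692). TiO2 day 1 replicate 6 stood apart for S100a9 at 4.98 against 2.99 to 3.70 (gap 0.641). TiO2 day 28 replicate 1 stood apart for Acadm at 1.18 against 2.18 to 2.74 (gap 0.64). TiO2 day 28 replicate 3 stood apart for Errfi1 at 1.90 against 3.27 to 3.82 (gap 0.71) and Nr4a1 at -3.11 against -2.36 to -2.03 (gap 0.689). Control day 1 replicate 1 stood apart for Acadl at 3.32 against 2.30 to 2.56 (gap 0.751), Acadm at 1.94 against 2.58 to 2.61 (gap 0.96), Cyp3a13 at 6.68 against 6.09 to 6.23 (gap 0.755), Hp at 5.67 against 6.65 to 6.82 (gap 0.852) and Saa2 at 3.45 against 4.72 to 5.01 (gap 0.811). Control day 1 replicate 3 stood apart for immediate early genes at -2.16 against -1.49 to -1.24 (gap 0.725). Control day 1 replicate 4 stood apart for Fdft1 at 2.21 against 1.73 to 1.86 (gap 0.729), Orm3 at 3.79 against 2.30 to 2.73 (gap 0.711) and Sqle at 1.48 against 0.86 to 0.93 (gap 0.897). Control day 28 replicate 1 stood apart for C3 at 5.99 against 5.66 to 5.70 (gap 0.871), Sowahb at 0.65 against -0.04 to 0.01 (gap 0.928) and neutrophil markers at -0.32 against -0.08 to -0.03 (gap 0.839). Control day 28 replicate 3 stood apart for Cd9 at -2.39 against -2.80 to -2.75 (gap 0.884) and Irf7 at -0.51 against 0.14 to 0.28 (gap 0.833). Control day 28 replicate 4 stood apart for Fgl1 at 6.26 against 5.84 to 5.91 (gap 0.834).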

How the results depend on the processing

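The alternatives with scan day as a block, with a scan day left out, with normexp on all spots, with scaling between arrays, on the arrays in range, with an estimated correlation and scan day, and all those for the lists of the difference between the days were chosen after seeing the data. Signal over background limits what these arrays show, since the number of liver probes above background differed by scan day. Named genes kept their direction and side of the threshold in 4613 of the values recomputed, passed it in 12 and turned sign in 155. Since no gene passed in the main fits, keeping that side says little about how firm a value is. Lists called kept both in 565, were no longer called in 109 and turned sign in 3. The list tally holds only camera at the preset correlation and leaves out the estimated correlation alone and fry, which called 0 lists. Both tallies include the void alternative named below. At day 1 the difference over all alternatives lay between 1.25 and 2.27 for Lcn2 (adjusted p 0.00038 to 1), 1.94 and 2.93 for Saa3 and 1.36 and 2.81 for Saa1. The acute phase list at day 1 lay between 0.26 and 0.66 and the cholesterol list at day 28 between 0.12 and 0.38, called in every alternative that kept the preset correlation. The interferon list of the controls lay between 0.076 and 0.34, also called in each of these. The glucocorticoid list of the difference between the days was lost without the arrays of scan day 2 (-0.039), and also with an estimated correlation and in fry. Quantile normalization of average intensities between arrays leaves each ratio as it was, so that alternative is void, and slide as a random block was not run for lists, because camera takes no such block. No paired analysis was possible because the replicate numbers follow the order of deposition and pair no animals. Where a sign turned or a count moved, the cause was not tested, and the genes whose sign turned had adjusted p of 0.702 to 1 there.

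At an unadjusted p under 0.05 and at least 1.5-fold, limma gave 31 genes for day 1, 9 for day 28, 12 for the difference between the days and 85 for the controls. With an estimated correlation camera called 0 lists in each comparison, and fry called 0. With an estimated correlation and scan day as a block camera called 2 lists for day 1, acute phase and glucocorticoid-responsive genes, and 0 in the others. The single gene called for day 1 with array weights, and that on the arrays in range, was Lcn2, at 1.58 and 1.90. Among the 7 called for the controls on the arrays in range, the named genes were Arntl at -1.29, Tle1 at 1.00 and Ppp1r3c at -1.78, named after their values were seen.

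With a normexp offset of 10, for day 1 the sign turned for Alb at 0.014. For day 28 camera called 3 lists. With the liver channel alone, for day 1 the sign turned for Alb at 0.068. For day 28 the sign turned for Alb at 0.049, C3 at 0.079, Hp at 0.26 and Saa1 at 0.069, and for the difference between the days the sign turned for Hp at 0.061. For the controls the sign turned for C3 at -0.047 and Saa2 at -0.099. With slide as a fixed block, for day 1 the sign turned for Alb at 0.034. For day 28 camera called 9 lists and the sign turned for Alb at 0.016, C3 at 0.10, Saa1 at 0.28 and Saa2 at 0.015. For the controls the sign turned for Alb at 0.12, Hp at 0.22, Mt1 at 0.026, Mt2 at -0.13, Saa1 at 0.18 and Saa3 at 0.45. With slide as a random block, for day 1 limma called 3 genes and the sign turned for Alb at 0.011. For day 28 the sign turned for C3 at 0.043 and Saa1 at 0.11. For the controls the sign turned for Alb at 0.028, Hp at 0.095, Mt2 at -0.054 and Saa3 at 0.17. With array weights, for day 1 limma called 1 gene, camera called 13 lists and the sign turned for Alb at 0.043 and Hmox1 at 0.045. For day 28 camera called 3 lists and the sign turned for C3 at 0.002, S100a9 at -0.061, Saa3 at -0.048 and sinusoidal endothelial cell markers at -0.024, and for the difference between the days the sign turned for Hmox1 at -0.19. For the controls limma called 8 genes, camera called 9 lists and the sign turned for Cyp7a1 at -0.043, Mt2 at -0.059 and Saa2 at -0.004. Without the arrays of scan day 1, for day 1 camera called 13 lists and the sign turned for Alb at 0.11. For day 28 the sign turned for C3 at 0.09, and for the difference between the days camera called 11 lists. For the controls camera called 12 lists and the sign turned for Alb at 0.082, C3 at -0.06 and Mt2 at -0.10. Without the arrays of scan day 2, for day 1 the sign turned for Hmox1 at 0.003. For day 28 the sign turned for Chil3 at -0.003 and Saa1 at 0.056, and for the difference between the days the sign turned for Hmox1 at -0.087. For the controls camera called 7 lists and the sign turned for Mt1 at 0.25 and Saa3 at 0.20. Without the arrays of scan day 3, for day 1 camera called 3 lists and the sign turned for Hp at -0.083. For day 28 camera called 3 lists and the sign turned for Hmox1 at 0.026, and for the difference between the days the sign turned for Alb at 0.054. For the controls the sign turned for C3 at -0.013 and Mt2 at -0.13. On the arrays that the quality report called in range, for day 1 limma called 1 gene, camera called 17 lists and the sign turned for Cpt1a at 0.15. For day 28 the sign turned for C3 at 0.06, Hsp90b1 at -0.13, Mt1 at 0.23, Pdia6 at -0.011, Saa3 at -0.11, Sdf2l1 at -0.20 and ER stress and unfolded protein response at -0.043, and for the difference between the days camera called 10 lists and the sign turned for Alb at 0.075. For the controls limma called 7 genes, camera called 11 lists and the sign turned for Cyp7a1 at -0.72, Mt2 at -0.12 and Saa2 at -0.18. With the scanner software's LogRatio, for day 28 camera called 3 lists and the sign turned for C3 at 0.067, Dnase1l3 at -0.35 and Mpo at -0.25, and for the difference between the days the sign turned for Alb at 0.13, Cyp7a1 at -0.43 and Hmox1 at -0.017. For the controls camera called 10 lists and the sign turned for C3 at -0.11, Cyp2c39 at 0.084, Cyp3a13 at 0.24, Fgl1 at 0, Mt2 at -0.17 and Saa2 at -0.002. With no background correction, for day 28 camera called 2 lists. With the authors' values, for day 28 camera called 3 lists and the sign turned for C3 at 0.041 and Hp at 0.013, and for the difference between the days the sign turned for Alb at 0.002 and Hmox1 at -0.17. With no filter on dim probes, for day 28 camera called 2 lists. With probes averaged per gene, for day 28 the sign turned for C3 at 0.01. For the controls the sign turned for C3 at -0.088. With scan day as a block, for day 28 the sign turned for C3 at 0.014, and for the difference between the days the sign turned for Hmox1 at -0.015. For the controls the sign turned for Alb at 0.001, Hp at 0.017 and Saa3 at 0. With normexp on all spots, for day 28 the sign turned for Dnase1l3 at -0.03, Saa1 at 0.34, Saa2 at 0.31, Saa3 at -0.008 and Vsig4 at -0.058, and for the difference between the days the sign turned for Hmox1 at -0.22. For the controls camera called 16 lists and the sign turned for Alb at 0.80, Cyp7a1 at -0.70, Hp at 0.29, Mt1 at 0.18, Saa2 at -0.64 and Saa3 at 0.028. With scaling between arrays, for day 28 the sign turned for C3 at 0.091, Hp at 0.014 and Saa1 at 0.008, and for the difference between the days the sign turned for Alb at 0.028.

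With each array left out in turn, the ranges for day 1 were the count of genes 0 to 3, the count of lists 3 to 13, Alb -0.11 to 0.059, Hmox1 -0.29 to 0.14, Hp -0.15 to 0.31 and immediate early genes -0.012 to 0.22. For day 28 they were the count of lists 3 to 8, Alb -0.23 to 0.015, C3 -0.036 to 0.074, Chil3 -0.008 to 0.28, Hmox1 -0.14 to 0.075, Hp -0.24 to 0.067, Saa1 -0.23 to 0.12, Saa2 -0.23 to 0.046 and Saa3 -0.11 to 0.18. For the difference between both effects they were the count of lists 3 to 7, Alb -0.21 to 0.037, Hmox1 -0.17 to 0.26 and Hp -0.38 to 0.077. For the controls they were the count of genes 0 to 1, the count of lists 3 to 11, Alb -0.18 to 0.032, C3 -0.012 to 0.15, Hp -0.27 to 0.11, Mt1 -0.48 to 0.15, Mt2 -0.45 to 0.46, Saa2 -0.11 to 0.29 and Saa3 -0.22 to 0.069. The count of genes moved without TiO2 day 1 replicate 2 (3) and control day 1 replicate 4 (1, for the controls). The count of lists moved by over 1.5 times for day 1 without control day 1 replicate 1 (13) and TiO2 day 1 replicate 6 (3), and for day 28 without replicate 2 of the control (8) or TiO2 mice (8) and replicate 3 of the control (3) or TiO2 mice (3). It did so for the difference between the days without control day 28 replicate 4 (3), and for the controls without control day 1 replicate 1 (11) and control day 28 replicate 4 (8).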

Other observations

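The tests of both days together, over all splits and within scan days, were chosen after the result was seen.

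Genes of bile acid synthesis and transport, the list that Cyp7a1 belongs to, had a mean difference of -0.14 (-0.54 to 0.27) at day 1, with 13 of 18 lower, and of -0.031 (-0.46 to 0.40) at day 28. Sinusoidal endothelial markers had -0.15 (-0.49 to 0.19) at day 1, with 13 of 15 lower, against 0.12 at day 28. Kupffer cell markers had 0.11 (-0.36 to 0.58) at day 1, with 12 of 15 higher. None of these 3 lists was called at day 1 by camera, and with scan day as a block Kupffer cell markers were (0.18, -0.17 to 0.53, and adjusted p = 0.689 with an estimated correlation). Genes of oxidative phosphorylation differed by -0.07 (-0.13 to -0.01) at day 1 with scan day as a block, when camera called them, and genes of gluconeogenesis by 0.13 (-0.031 to 0.29), also called there, where the adjusted p = 0.34 and 0.588 with an estimated correlation. The hepatocyte marker list had -0.10 (-0.68 to 0.47) at day 1 and -0.036 (-0.65 to 0.57) at day 28, and the lung marker list 0.034 (-0.074 to 0.14) and -0.028 (-0.14 to 0.086).

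Over both days, with mice exchanged within each day, Lcn2 had a mean difference of 0.93 and Cyp7a1 of -1.38, whose other probe gave -0.41 at day 1 and -0.56 at day 28. The exact permutation p, two-sided and adjusted over the 10 fixed genes with complete values, was 0.00402 for Lcn2 and 0.0188 for Cyp7a1, over 97020 splits. It was 0.051 for Saa3 at 1.23 and 0.0655 for Saa1 at 0.88. Most of these means came from day 1, at 2.41 for Saa3, 1.77 for Saa1 and 1.48 for Lcn2, against 0.054, -0.013 and 0.37 at day 28. For Cyp7a1 the differences were -1.60 and -1.16. The day 28 part for Lcn2 cannot be told apart from the level of the day 28 controls, which lay below those of day 1. With mice exchanged only within a day and a scan day (5832 splits) the differences were 0.96 for Lcn2, -1.48 for Cyp7a1, 1.26 for Saa3 and 0.94 for Saa1, with adjusted exact p of 0.0154, 0.0223, 0.0745 and 0.0745. Mt1 had -0.007 and Mt2 -0.12, with differences of opposite sign on the 2 days.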
